A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

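Histone H3 dimethylated at lysine 9 (H3K9me2), a mark of heterochromatin, was mapped in the fission yeast Schizosaccharomyces pombe by chromatin immunoprecipitation on tiling arrays (ChIP-chip). Per the labels' protocols, log-phase cultures in rich medium at 30 °C were fixed in 3% paraformaldehyde, and chromatin was sheared to between 500 and 1000 bp. It was precipitated with either of a pair of H3K9me2 antibodies, and the labels do not say which one was used for which array. Amplified immunoprecipitated DNA carried Cy5 and whole-cell extract DNA (the input) carried Cy3, per the labels, on a custom array of 60-nt probes at about 300 bp intervals. The 6 arrays comprised 3 of wild type, 1 of a taz1 deletion and 2 of a rif1 deletion. The labels number the arrays by series: wild type and taz1 deletion in series 1, and wild type and rif1 deletion in each of series 2 and 3. Per the file headers, the arrays of series 2 shared slide 3, those of series 3 shared slide 4, and the arrays of series 1 lay on slides 1 and 2. The labels do not say whether the series were separate cultures, so p-values measure only the spread between these arrays.

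The deposited scanner files hold intensity per spot and channel. Per the file headers, the processed intensity was background-subtracted, detrended and dye-normalised by Agilent Feature Extraction 9.5.1.1 (wild type 1), 9.5.3.1 (taz1 deletion 1), 11.5.1.1 (series 2) and 12.0.3.1 (series 3). The multiplicative detrend was applied to the green channel alone in rif1 deletion 2, per the file headers. The deposited series values hold the log2 ratio of the processed Cy5 over Cy3 signals. They were checked against the log ratios of the scanner files, and 100% of the genomic probes of 5 arrays and 99.99% in rif1 deletion 2 were equal within 0.001. Neither the files nor the labels name the genome build of the array design. Probe sequences were therefore matched exactly to the ASM294v3 reference, on which all coordinates and gene names are given. Of 41551 genomic probes 41449 matched, 1053 of them at several places, and 102 had no match.

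From these files, log2(Cy5/Cy3) was computed from the processed signals, and each array was centred on its median over genomic probes. Spots that the scanner software marked as outliers were taken as missing (17.56% of the spots in wild type 1, and at most 0.53% in any other array). A missing spot was filled by an additive fit of probe and array within its domain or gene. Red signal over background was 58.7 in wild type 1, 176 in taz1 deletion 1, 11.3 and 11.2 in series 2, and 22.8 and 34.7 in series 3 (wild type first). The number of arrays limits the precision.

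H3K9me2 domains were runs of at least 4 probes, joined over gaps of 1 probe and not across more than 1500 bp, in which the running median over 5 probes of the mean of all 6 arrays reached 1.5-fold. Domains were classed by position. The centromere windows were 3.7 to 3.9 Mb on chromosome I, 1.5 to 1.7 Mb on II and 1.0 to 1.2 Mb on III, and the mating-type window was 2.1 to 2.2 Mb on II. Subtelomeres lay within 100 kb of the ends of I and II, and rDNA flanks within 100 kb of the ends of III. All other domains were called islands. Each domain took the name of the gene under its highest probe, or of the nearest gene. Gene values were means over probes inside a gene with at least 2 probes.

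Group differences were tested with limma 3.58.1 (R 4.3.3) on all 6 arrays, per domain, probe and gene, with Benjamini-Hochberg adjustment at 0.05. The lone taz1 array was assumed to vary like the others. Fits with series as a block were also chosen before the data were examined, with the pairing taken from the labels' series numbers. As a check, the difference between wild type 2 and 3 was correlated with that between rif1 deletion 2 and 3. This gave r = 0.777 across domains, 0.322 across probes and 0.261 across probes outside domains. It covers series 2 and 3 alone, whose paired arrays share a slide, and says nothing of the pairing in series 1. The block fit has limits: it had 1 residual degree of freedom against 3 without the block, it gave all domains a single shared spread, and series 1 added nothing to that spread. The fit without the block had 3.83 prior degrees of freedom. Class means were compared between rif1 deletion and wild type by a two-sided exact permutation test over 10 splits, whose smallest p is 0.1. The taz1 class values had no test. Gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. The latter rests on the residual degrees of freedom, 3 without the block and 1 with it, so few lists could pass it.

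Recovery was tested on simulated data with differences between series as large as the real ones. Of domains changed by 2 on the log2 scale, 4% were found without the block and 74% with it for the taz1 contrast, and 11% and 95% for the rif1 contrast. At a change of 4, these shares were 67%, 98%, 89% and 100%. With the same spread for all domains, 0.578% of taz1 calls and 2.01% of rif1 calls with the block were false. With spreads that varied between domains, 7.48% and 9.55% were false, above the 5% aimed for, and among 4936 genes 9.62% and 9.17% (24.5% and 30.6% where series did not differ). Among 33940 probes with such varied spreads, 0% of taz1 changes of 4 were found with or without the block. For rif1, 76% were found without the block and 89% with it, and 5% and 13.3% of calls were false. These simulations varied the evenness of the spread and the differences between series, and used the same noise level for both contrasts. They did not vary the enrichment of a whole array, or the spread between paired arrays on separate slides, as for taz1. The false shares for taz1 therefore cannot be taken as those of its real calls with the block.

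Lists, classes, tests and the rule for naming genes were fixed before the data were examined. The rule took, for each contrast with wild type, the deleted gene, then the 10 largest falls and 6 largest rises among islands past the threshold. Where fewer passed, the islands with the largest differences filled 8 places. It also took the largest fall and rise of each class and the 4 genes of smallest p in each list. The lists were Mmi1 targets, other meiosis genes, known island genes, phosphate genes, genes within 50 kb of the ends of chromosomes I and II, Tf2 retrotransposons, mating cassettes, background controls, strain markers, heterochromatin factor genes and shelterin genes. Symbols absent from the annotation were looked up among its synonyms (mcp5 as num1, tub1 as atb2).

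Telomere-like repeats were sought as at least 2 copies of GGTTAC on a strand within 40 bp, and islands were compared with 1000 random placements. Other settings covered the centring, scaling to the centromeres, the deposited series values, loess, dim or saturated probes, blocks by series and slide, only the groups compared, each wild-type or rif1 array left out, domain definitions, the median over probes, eBayes options, a threshold of 0.1, the Spearman correlation and the repeat definition. Normexp (offset 50) was planned on mean signals, which the files do not hold, and was run on median signals. Computations and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (version 1.17.8).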

Results

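H3K9me2 was measured in 6 arrays: 3 of wild-type fission yeast, 1 of cells without taz1 and 2 of cells without rif1. Taz1 binds telomeric repeats as part of shelterin, and Rif1 acts at telomeres and in the timing of replication origins. The title of the series asks whether Taz1-shelterin promotes facultative heterochromatin at internal sites with late origins. Values are log2 ratios of immunoprecipitated over whole-cell extract DNA, and differences are mutant minus wild type. There is no replicate of the taz1 deletion, so its values carry no spread of their own.

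The arrays matched their labels. Over the taz1 gene (I, 3091021 to 3093260), the whole-cell extract stood at -7.13 in the taz1 deletion and between 0.07 and 0.57 in the other arrays. Over rif1 (I, 2766273 to 2770704), it stood at -2.83 and -2.80 in the rif1 deletions and between -0.0027 and 0.77 elsewhere. Where DNA is missing, the ratio is no measure of H3K9me2: over the taz1 gene it read 2.96 in the deletion.

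H3K9me2 formed 112 domains: 35 at centromeres, 24 at subtelomeres, 6 in the mating-type window, 7 beside the rDNA and 40 islands. Other definitions gave 57 domains with 17 islands (2-fold), 137 with 64 (wild-type mean) and 98 with 36 (mean of group means). The 40 include the domain at taz1, which read 0.02, 0.13 and 0.31 in wild type and 4.05 in the taz1 deletion, where input DNA is missing. In wild type the mean ratio was 3.27 ± 0.89 at centromeres, 3.899 ± 1.181 at subtelomeres, 2.38 ± 0.56 in the mating-type window and 1.68 ± 0.66 over islands (SD, n = 3). Wild-type arrays differed between series by more than many mutant differences. Centromeres read 4.15, 2.38 and 3.28 in wild type 1, 2 and 3.

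**Figure D1:**
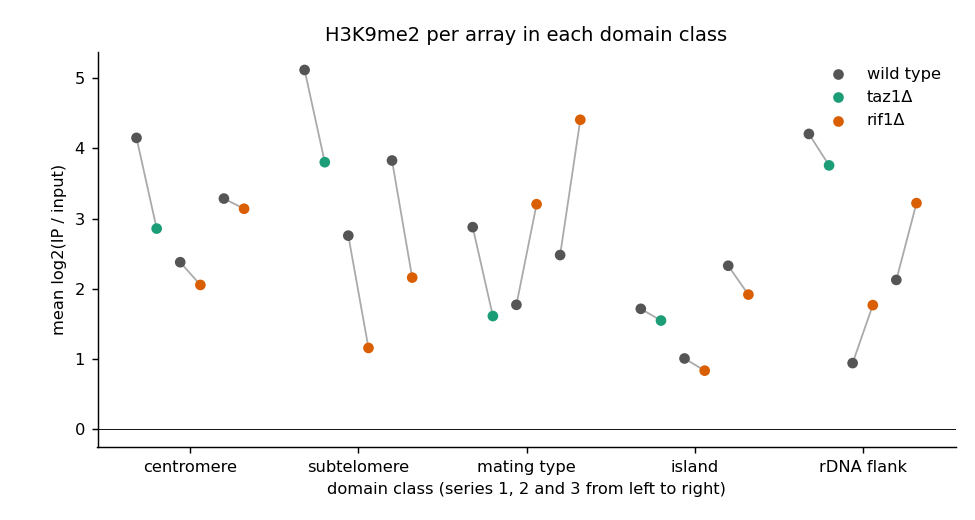
Mean log2 ratio of immunoprecipitated over input DNA (vertical axis) in each domain class (horizontal axis), with a point per array and a line joining the arrays of a series. Subtelomeres read 1.16 and 2.16 in the rif1 deletions against 2.76 and 3.83 in wild type of the same series.

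The first comparison, taz1 deletion against wild type, asks where H3K9me2 depends on Taz1. The clearest differences within series 1 were at chromosome ends and at a few isolated loci. On the right end of chromosome I (I, 5529990 to 5556662), H3K9me2 read 8.01 in wild type 1 and 2.15 in the taz1 deletion. The input there was low in wild type 1 (-2.04 against -0.40), which raised its ratio, and the immunoprecipitate alone differed by -4.24. In the outermost part of the same end (I, 5556985 to 5579096), where 12 of 67 probes match a single place, the mean was 6.49 against 7.79. Of these 12, the 9 nearest the inner part (I, 5556985 to 5559353) read 2.82 against 7.27, and the 3 farther out (I, 5562152 to 5573164) read 7.18 against 7.88. The left end of I, which holds the telomere-linked helicase gene tlh1 (I, 112 to 49396), read 6.36 against 6.28. In the tlh1 domain 136 of 159 probes match several places. With centromere scaling and the block it was higher by 2.11. That scaling multiplies log ratios, so it raises enriched domains whose ratios were alike in both arrays.

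**Figure D2:**
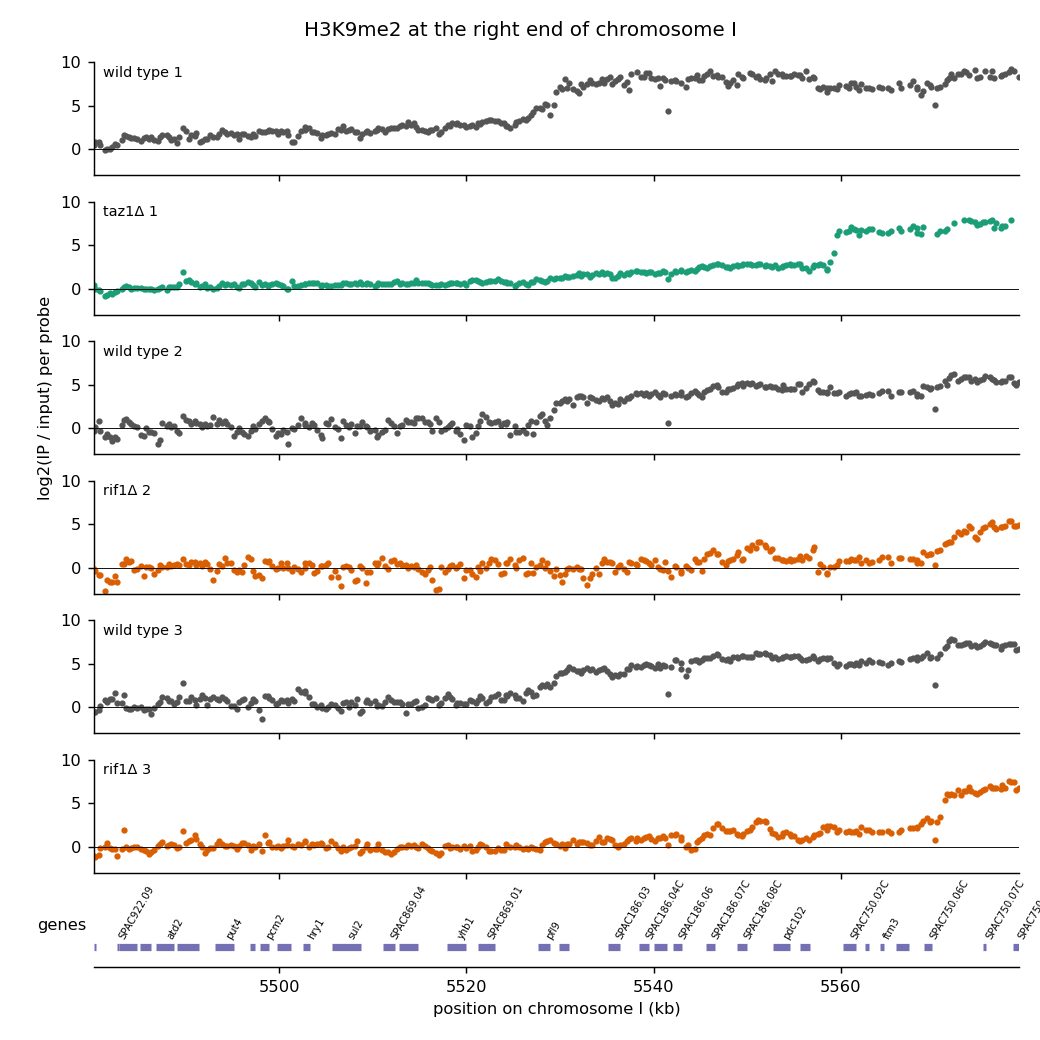
Log2 ratio per probe (vertical axes) along the right end of chromosome I in kb (horizontal axis) in each of the 6 arrays, with protein-coding genes as bars. Over the inner part the taz1 deletion read 2.15 against 8.01 in wild type 1, and the rif1 deletions read 0.62 and 1.11 against 4.04 and 5.02.

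No domain passed the adjusted threshold in the taz1 deletion in limma without the block (0 of 112; 3 at an unadjusted p under 0.05; smallest adjusted p = 0.0637). With series as a block, 33 domains passed, 31 of them lower. The block fit set the mutant against wild type 1, with a standard error of 0.47 shared by all domains. That spread came from series 2 and 3, whose paired arrays shared a slide, while the arrays of series 1 lay on separate slides. It may therefore be too small for series 1. With slide as a random block, as without a block, no domain passed in the taz1 deletion. The lower domains were 17 at centromeres, 8 at subtelomeres, 2 in the mating-type window and 4 islands. At the right end of I, the domain of SPAC750.08C fell by 3.87 (without the block -1.92 ± 1.30, SE). On the left arm of II, SPBPB21E7.09 fell by 5.52 and SPBC1348.08C rose by 2.47. With arrays scaled to their centromeres, which sets the centromere class near 0 by construction, and the same block, 17 domains passed, 6 lower and 11 higher. That setting cannot say whether H3K9me2 fell at centromeres. It multiplies log ratios, by more in the taz1 deletion than in wild type 1. Enriched domains with like ratios in both arrays therefore read as higher.

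Among the islands, 4 fell in the taz1 deletion with the block. These were avl9 (I, 2520754 to 2522942; -1.39, adjusted p = 0.0156), iec1 (I, 4653039 to 4654341; -1.54, adjusted p = 0.00848), coa6 (II, 2338359 to 2341137; -2.36, adjusted p = 3.8e-05) and ura4 (III, 114804 to 117375; -1.48, adjusted p = 0.0106). Iec1 is a subunit of the Ino80 chromatin remodeller, and ura4 is a uracil synthesis gene used as a strain marker. Over the ura4 gene wild type 1, 2 and 3 read 8.33, 5.41 and 7.01, above centromeres on the same arrays. The input there stood at -6.23 in rif1 deletion 2. Probes cannot tell the gene at its own site from a copy placed elsewhere, and the labels do not give the genotype. The ura4 values may therefore reflect strain differences at this marker rather than an island. After centromere scaling with the block, coa6 kept its call (-1.64, adjusted p = 0.00886), whereas avl9 (-0.996, adjusted p = 0.122) and iec1 (-1.17, adjusted p = 0.0689) lost theirs, and ura4 turned to 0.51 (adjusted p = 0.472). A pair of similar domains fell inside other windows: eno101, an enolase gene, in the mating-type window (II, 2197307 to 2200968; -1.89), and erm1 in a centromere window (III, 1037311 to 1040676; -1.78). After centromere scaling with the block, eno101 kept its call (-1.36, adjusted p = 0.0325) and erm1 lost it (-1.22, adjusted p = 0.0543). The island at taz1 itself read 4.04 higher, where the input DNA is missing, and its immunoprecipitate channel alone gave -5.21 without the block.

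The islands at mei4, mcp7, ssm4, num1 and SPAC8C9.04 did not pass in the taz1 deletion in either fit without scaling. Within series 1, the island of mei4, a meiotic transcription factor gene (II, 1470966 to 1475867), differed by -0.30, mcp7 (I, 577847 to 581563) by 0.31, ssm4 by 0.29, num1 by 0.49 and SPAC8C9.04 by 0.30. With centromere scaling and the block, mcp7 (1.36, adjusted p = 0.0325), ssm4 (1.42, adjusted p = 0.0306) and num1 (1.31, adjusted p = 0.0384) passed as higher, and mei4 (0.97, adjusted p = 0.128) and SPAC8C9.04 (1.05, adjusted p = 0.109) did not pass. The scaling multiplies log ratios, so enriched islands with like ratios in both arrays of series 1 read as higher. It moved the median of the 35 islands other than taz1 and those that fell from -0.053 to 0.285. These rises are therefore no sign of gained H3K9me2. Without the block, mei4 differed by 0.78 ± 1.07 and mcp7 by 1.49 ± 1.24 (SE). The other islands named by size without the block were rfc3 (-1.75), SPBC1105.13C (-1.54) and rad2 (-0.99). The block fit gave -0.07, -0.38 and -0.23 for them, and none passed. The rfc3 island was present only in series 3, at 5.85 in wild type 3 against -0.12 and -1.04 in wild type 1 and 2.

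**Figure D3:**
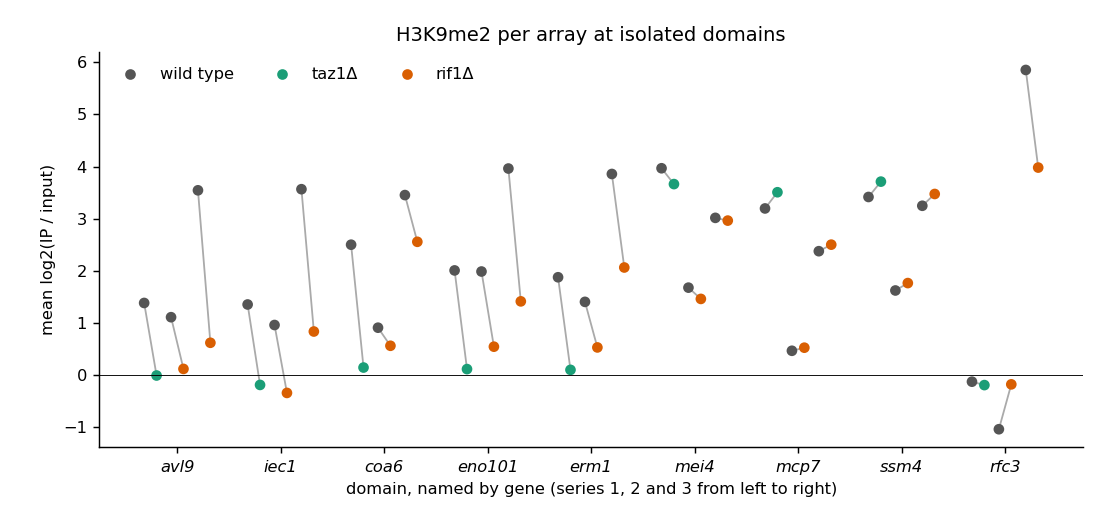
Mean log2 ratio of immunoprecipitated over input DNA (vertical axis) at isolated domains (horizontal axis), with a point per array and a line joining the arrays of a series. At avl9 the taz1 deletion read 0.00 against 1.39, and the rif1 deletions read 0.12 and 0.62 against 1.11 and 3.55, while ssm4 differed by 0.29, 0.14 and 0.23.

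As classes, the taz1 deletion lay within the range of the wild-type arrays at centromeres (2.86), subtelomeres (3.80), islands (1.55) and rDNA flanks (3.76). It lay below that range in the mating-type window (1.61 against 1.77 to 2.88). Differences from the wild-type mean were -0.41, -0.10, -0.14, 1.33 and -0.76 in that order, and from wild type 1 alone they were -1.29, -1.31, -0.17, -0.45 and -1.27. Against the wild-type mean, scaling to centromeres turned the subtelomere and island differences to 0.43 and 0.08. Against wild type 1 alone, the same scaling also turned the subtelomere and island differences positive, and it shrank the fall in the mating-type window. Loess turned those at centromeres, subtelomeres and islands to 0.36, 0.67 and 0.24, and normexp turned that at subtelomeres to 0.08. Leaving out wild type 1 gave 0.03 at centromeres and 0.51 at subtelomeres, leaving out wild type 2 gave -0.86, -0.67 and -0.47 at centromeres, subtelomeres and islands, and leaving out wild type 3 gave 0.19 at islands. Without the block, differences of single domains ran from -2.28 (erm1) to 0.37 (emc5) at centromeres, from -2.89 (SPBPB21E7.09) to 2.80 (SPBC1348.08C) at subtelomeres and from -0.40 (SPCC569.03) to 1.81 (SPCP20C8.01C) beside the rDNA. In the mating-type window they ran from -2.54 (eno101) to -0.09 (nvj2).

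By gene, none of 4936 passed in the taz1 deletion without the block in limma (28 at an unadjusted p under 0.05), and 19 passed with it, 14 lower and 5 higher. Of 41172 probes 0 passed without the block (298 at an unadjusted p under 0.05) and 129 with it, 109 lower and 20 higher. With centromere scaling and the block 0 passed (449 at an unadjusted p under 0.05). Genes near the ends of I and II divided. With the block, SPAC186.08C fell by 5.46, while SPAC977.05C (3.74), SPBC1348.06C (3.67) and SPBPB2B2.15 (3.89) rose. The genes that rose hold 3, 2 and 2 probes and read alike, at 1.97, 2.00 and 2.14 in wild type and 6.1, 6.3 and 6.4 in the taz1 deletion. Signal shared between copies was not separated, so they may not be independent rises. Of 46 measured genes in this list, 9 fell and 4 rose with the block, and 6 passed without it when adjusted over the list alone (15 with the block). Both measured mating cassettes fell with the block, mat1-Mc by 2.35 and mat3-Mc by 2.43. These share sequence.

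Camera called 7 of 11 lists in the taz1 deletion without the block, and none held with an estimated correlation (smallest adjusted p = 0.270 with an estimated correlation). Without wild type 2 the count was 4. The called lists were subtelomere genes (adjusted p = 1.8e-09, median 1.04), shelterin genes (adjusted p = 0.000244, median 0.31), Mmi1 targets (adjusted p = 0.00123, median 0.56), Tf2 retrotransposons (adjusted p = 0.00226, median 0.29), mating cassettes (adjusted p = 0.0261, median -1.03), known island genes (adjusted p = 0.0300, median 0.86) and heterochromatin factor genes (adjusted p = 0.0372, median 0.18). With an estimated correlation their adjusted p-values were 0.433, 0.270, 0.314, 0.433, 0.314, 0.433 and 0.314. With the block 5 lists were called at the preset correlation. Subtelomere genes turned downward (adjusted p = 1.2e-15, median -0.39) and strain markers were called lower (adjusted p = 0.00549), while mating cassettes, shelterin genes and Mmi1 targets kept their direction. Known island genes (adjusted p = 0.518), Tf2 retrotransposons (adjusted p = 0.889) and heterochromatin factor genes (adjusted p = 0.267) were not called. None of the 5 held with an estimated correlation (smallest adjusted p = 0.526 with an estimated correlation). With centromere scaling and the block, subtelomere genes (adjusted p = 2.8e-47), known island genes (adjusted p = 4.4e-23), Mmi1 targets (adjusted p = 2.3e-16), shelterin genes (adjusted p = 0.000804) and Tf2 retrotransposons (adjusted p = 0.00783) were called higher, and mating cassettes (adjusted p = 0.815) and strain markers (adjusted p = 0.440) were not called. None of these held with an estimated correlation (smallest adjusted p = 0.458 with an estimated correlation). The scaling multiplies log ratios, so lists of enriched genes read higher even where ratios were alike in both arrays of series 1. The taz1 gene, where input DNA is missing, is a member of the shelterin list. That list did not hold although its estimated correlation (-0.138 without the block) lay below the preset 0.01. The tests with an estimated correlation have few degrees of freedom, so they cannot say whether correlation between genes explains the calls. Among Mmi1 targets, meiotic transcripts removed in growing cells, mug8 (0.77), mug10 (0.36), ssm4 (1.27) and mcp7 (1.89) had the smallest p and none passed. Uncalled without the block were other meiosis genes (median 0.18; spo4 0.46, meu13 0.31, mei3 0.26, ste11 0.20), phosphate genes (median 0.17; pho1 0.93, pho84 0.35), background controls (median 0.15; cdc25 0.26, tdh1 0.26) and strain markers (median -0.18; lys1 -0.77, ade2 -0.19). Apart from subtelomere genes and shelterin genes (1, the taz1 gene), 0 genes passed when adjusted over the list alone without the block.

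The second comparison, rif1 deletion against wild type, asks which H3K9me2 depends on Rif1. Beside mat1 (II, 2113528 to 2122885) both rif1 deletions read above wild type of the same series. Over the 50 of 60 probes with a single match they read 5.66 and 7.12 against 0.76 and 1.32, with 1.52 in wild type 1 and 0.56 in the taz1 deletion. Over all 60 probes, the others of which match several places, these were 5.64 and 7.13 against 1.47 and 2.14. The genes SPBC23G7.10C (5.74 ± 0.42, adjusted p = 0.00239), mag2, a DNA glycosylase gene (4.96 ± 0.51, adjusted p = 0.0151), and rpt6, a proteasome ATPase gene (4.73 ± 0.50, adjusted p = 0.0151), rose without the block (SE). They were the 3 of 4936 genes that passed, and were chosen after their values were seen. The whole-cell extract of this region was lower by a difference of -2.15 in series 3 and of -0.21 in series 2. Low input raises the ratio. Over the probes with a single match the immunoprecipitate alone differed by 4.66 in series 2 and 3.50 in series 3.

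**Figure D4:**
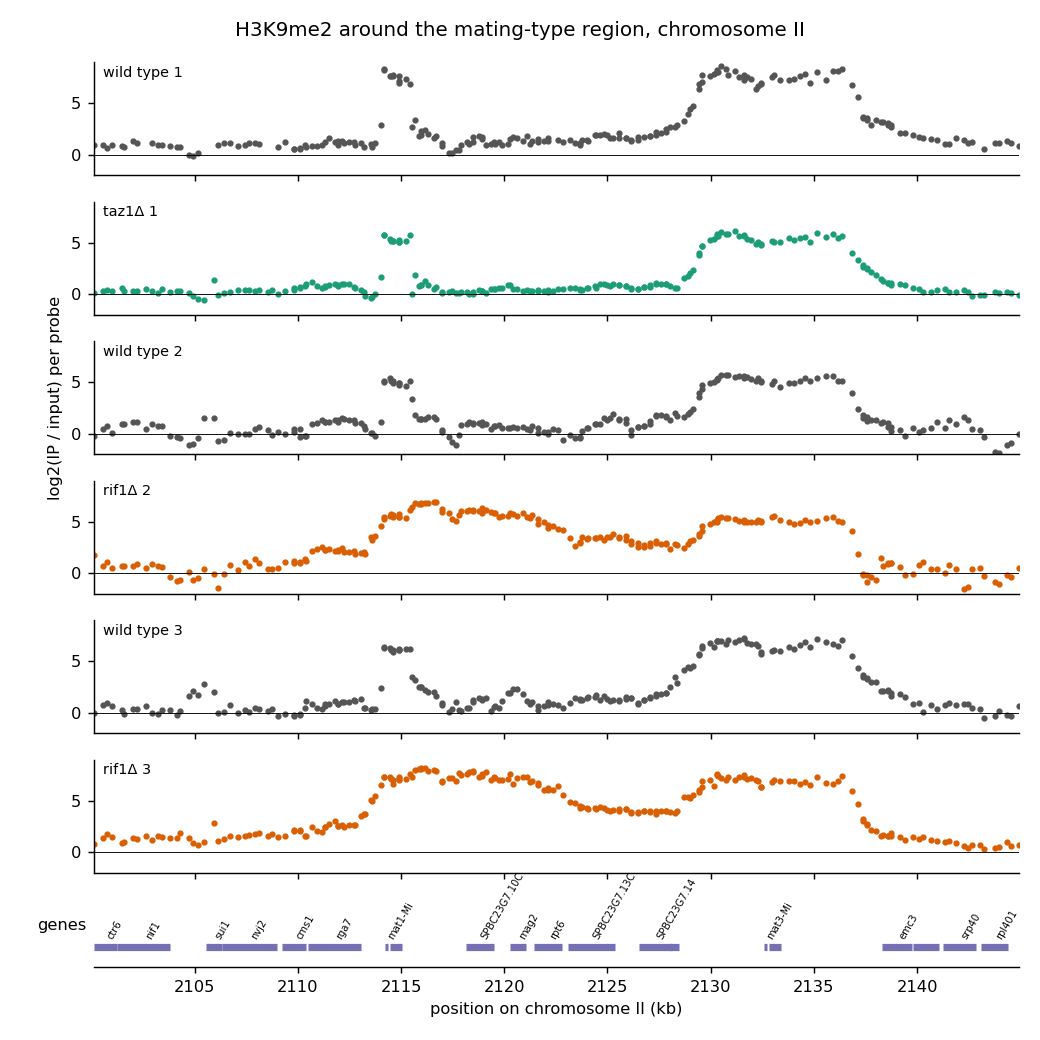
Log2 ratio per probe (vertical axes) along chromosome II around the mating-type region in kb (horizontal axis) in each of the 6 arrays, with protein-coding genes as bars. Between mat1 and mat3 the rif1 deletions carried H3K9me2 over SPBC23G7.10C, mag2 and rpt6, at 5.66 and 7.12 over the probes with a single match beside mat1 against 0.76 and 1.32 in wild type of the same series.

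Subtelomeres read lower in both rif1 deletions. The class mean was 1.66 ± 0.71 (SD, n = 2) against 3.899 ± 1.181 (SD, n = 3), a difference of -2.24 (exact permutation p = 0.2), and within series it was -1.60 and -1.67. On the right end of I the differences were -3.42 and -3.91, over tlh1 -1.66 and -1.43, and at SPBC1348.01 on the left end of II -3.00 and -2.96. The mating-type class differed by 1.43 (exact permutation p = 0.1, the smallest possible), and by 1.43 and 1.93 within series. It was 0.83 without rif1 deletion 3, 2.24 with centromere scaling and 0.45 as a mean over domains of the median over probes, a setting that gave -1.34 at subtelomeres. Centromeres differed by -0.67 (exact permutation p = 0.4), islands by -0.31 (exact permutation p = 0.7) and rDNA flanks by 0.07 (exact permutation p = 1.0). Within series, centromeres differed by -0.32 and -0.15, islands by -0.17 and -0.41, and rDNA flanks by 0.83 and 1.09. The centromere difference was -0.13 without rif1 deletion 2, -1.22 without rif1 deletion 3, -0.23 without wild type 1 and -1.12 without wild type 2. The island difference was 0.23, -0.85, -0.29 and -0.65 in that order, and 0.01 without wild type 3.

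No domain passed in the rif1 deletion in limma without the block (0 of 112; 6 at an unadjusted p under 0.05; smallest adjusted p = 0.494). With series as a block, 20 passed, 13 lower and 7 higher, with a standard error of 0.33 shared by all domains. With slide as a random block 17 passed. The lower ones were 7 subtelomeric domains, 4 islands, erm1 at a centromere (-1.33) and eno101 in the mating-type window (-1.99). The higher ones were rpp202 (2.16), which spans mat1, nvj2 (1.11), the island mas2 (0.91) and 4 domains beside the rDNA. Of 41390 probes 56 passed without the block, 8 lower and 48 higher, and 47 of the higher ones lay beside mat1 with a median of 5.44. Of the 8 lower probes, 6 lay at the right end of I. Some settings called more lower than higher probes: 289 against 97 with the block, and 240 against 77 with centromere scaling and 79 against 52 with loess, both without the block. Without the block the split was 96 against 49 if wild type 1 was left out and 258 against 51 if wild type 2 was. It was 0 against 27 if rif1 deletion 3 was left out, 0 against 38 if wild type 3 was and 0 against 44 if rif1 deletion 2 was.

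The islands that fell in the rif1 deletion with the block were avl9 (-1.96, adjusted p = 5.2e-07), iec1 (-2.02, adjusted p = 3.2e-07), ura4 (-1.36, adjusted p = 0.00076) and SPAPB1A11.02 (-0.92, adjusted p = 0.0361). SPAPB1A11.02 and mas2 were named after their values were seen. Within series, avl9 differed by -0.99 and -2.92 and iec1 by -1.30 and -2.73. At the ura4 gene the whole-cell extract of rif1 deletion 2 differed by -6.25 from that of wild type 2, so its ratio there is no measure of H3K9me2. In rif1 deletion 3 the whole-cell extract differed by -1.92 from that of wild type 3, the ratio by 0.54 and the immunoprecipitate by -1.38. Coa6 differed by -0.62 with the block and did not pass (adjusted p = 0.257). The other islands named by size without the block were mae2 (-0.80), num1 (-0.68), mei4 (-0.67) and hpz2 (-0.67), none past the threshold in either fit. With the block mae2 differed by -0.03, num1 by -0.61, mei4 by -0.13 and hpz2 by -0.56. Also uncalled in both fits were mcp7 (-0.50 without the block), rfc3 (0.34), rad2 (0.13) and SPBC1105.13C (-0.05).

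Without the block, differences of single domains in the rif1 deletion ran from -1.15 (rpb1) to -0.02 (SPBC21B10.08C) at centromeres and from -3.77 (SPBPB21E7.09) to -0.09 (SPBPB8B6.05C) at subtelomeres. In the mating-type window they ran from -1.67 (eno101) to 1.86 (rpp202), among islands from -1.99 (ura4) to 0.59 (mas2) and beside the rDNA from -0.26 (mug9) to 0.48 (SPCP20C8.01C). With the block 41 genes passed, 36 lower and 5 higher.

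Of 46 measured subtelomere genes, all 46 had negative differences in the rif1 deletion, with a median of -3.86, and 35 passed without the block when adjusted over the list alone. Over all genes 0 of them passed without the block (limma; 173 of 4936 genes at an unadjusted p under 0.05) and 31 fell with it. SPAC186.08C read -4.88 ± 0.78, SPBPB2B2.18 -4.01 ± 0.68, SPBC1348.15 -3.77 ± 0.52 and SPAC212.04C -2.87 ± 0.50 (SE) without the block. In the tlh1 domain only 23 of 159 probes match a single place, so genes of this list are not all separate measurements. Camera called this list alone without the block (adjusted p = 1.2e-67), with adjusted p = 0.467 with an estimated correlation. With the block it called mating cassettes as well, upward (adjusted p = 0.0281, and adjusted p = 0.632 with an estimated correlation). Medians of the other lists were -0.31 for Mmi1 targets, -0.69 for known island genes, 0.09 for other meiosis genes, -0.10 for phosphate genes, -0.22 for Tf2 retrotransposons, 0.09 for mating cassettes, 0.31 for background controls, -0.25 for strain markers, 0.10 for heterochromatin factor genes and -0.01 for shelterin genes. None of their genes passed when adjusted over the list alone without the block. Among them, mei4 (-1.001), vps29 (-1.12), mug9 (-0.63), crs1 (-0.39), spo5 (0.26), spo4 (0.56), meu13 (0.45), swi6 (0.40), clr3 (0.43), poz1 (0.58), atb2 (0.55), fba1 (0.62), pgk1 (0.47), adh1 (0.47), Tf2-2 (-0.37) and lys1 (-0.75) were among the 4 genes of smallest p in their lists. The background control act1 (II, 1475485 to 1477333) overlaps the mei4 domain at its edge and eno101 lies beside a domain, so these are not clean controls.

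The third comparison set the deletions against each other. The taz1 gene domain alone passed without the block (rif1 minus taz1 -4.35, adjusted p = 0.0476), where the taz1 strain lacks the DNA. The count was 0 without wild type 1, wild type 3 or rif1 deletion 2, and 2 without wild type 2. With series as a block 12 domains passed, 4 lower and 8 higher. In the rif1 deletion the tlh1 domain was lower than in the taz1 deletion by a difference of -1.63, SPBC1348.01 by -3.12 and SPBC1348.08C by -3.15. SPBPB21E7.09 (3.07), coa6 (1.73), rpp202 (3.47) and yhb1 (1.77) were higher. These values are without centromere scaling. With it and the block, the taz1 and rif1 differences from wild type were -3.56 and -2.57 at SPBPB21E7.09, -1.64 and -0.51 at coa6, and -1.40 and -0.43 at yhb1. These gaps narrowed. The gaps at tlh1 (2.11 and -1.39), SPBC1348.01 (2.32 and -3.08) and SPBC1348.08C (3.06 and -0.80) widened. The block comparison sets taz1 minus wild type 1 against rif1 minus wild type 2 and 3.

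Across the 40 islands, which are not independent replicates, taz1 minus wild type 1 correlated with rif1 minus wild type 2 at r = 0.26 (rho = 0.14) and with rif1 minus wild type 3 at r = 0.05 (rho = -0.15). Without the taz1 and ura4 islands r was 0.31 and 0.12 (rho = 0.12 and -0.17), and with centromere scaling 0.08 and 0.17 (rho = 0.06 and 0.16). These pairs share no control. The rif1 differences of series 2 and 3 correlated at r = 0.34. Against the shared wild-type mean the taz1 and rif1 differences correlated at r = 0.04, and simulated unchanged groups with shared controls gave a mean r of 0.30. The simulation drew each array independently, without the series differences that a mutant array shares with its own wild type. Its 0.30 is therefore no yardstick for the 0.04. None of the 40 islands held a telomere-like repeat inside or within 2 kb, against a mean of 0.39 in random placements, and the nearest lay 8.68 kb away. The genome held 20 such internal sites with 2 copies. With so few sites, finding none at the islands does not set them apart from random placements. The 4 islands that fell with the block in the taz1 deletion and the other 36 all lacked the repeat, so Fisher's exact test (p = 1.0) could not separate them.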

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

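All tests of explanations in this part were chosen after the results were seen, as were the 6 loci and both regions they concern. The first pattern is lower H3K9me2 in the taz1 deletion at avl9, iec1, coa6, ura4, eno101 and erm1, with a median difference from wild type 1 of -1.66 against -0.05 at the 35 islands other than these and taz1. Less enrichment on the taz1 array as the whole cause was weighed with centromere scaling and the block. That setting left coa6 at -1.64 and eno101 at -1.36 (SE 0.46), and both kept their calls. These loci were set apart from the others by that same outcome, so it is no separate test of that cause. With scaling, avl9 moved from -1.39 to -0.996, iec1 from -1.54 to -1.17, erm1 from -1.78 to -1.22 and ura4 from -1.48 to 0.51. Their median was -1.08 after scaling, and their calls ended at a like SE. Apart from ura4, all the loci lay between -1.64 and -0.996 after scaling, below the lowest of the 35 islands (-0.577). They were picked as low on the same arrays, so that cause stays open at avl9, iec1, erm1 and ura4. Whether the ura4 signal came from its own site was not tested. Missing DNA was argued against by a median whole-cell extract difference of -0.0478 over the 6 loci (SD over the other islands 0.144). A dependence of coa6 and eno101 on Taz1 is a hypothesis from 1 taz1 array and loci picked by their values. In the rif1 deletions coa6 differed by -0.35 and -0.90 without passing (limma with the block, adjusted p = 0.257). Rif1 minus taz1 was 1.73 there with the block and without scaling. With centromere scaling and the block coa6 differed from wild type by -1.64 (taz1) and -0.51 (rif1), a smaller gap between the deletions.

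The second pattern is H3K9me2 beside mat1 in both rif1 deletions. Loss of input signal was argued against by the immunoprecipitate channel, higher by at least 2.85 in both series (SD over islands 0.49). The whole-cell extract differed by -0.21 in series 2, where a doubled region would lie near 1 if input followed copy number alone. At the right end of I, where the ratio fell, the input rose by 1.64, 0.32 and 0.63 in series 1, 2 and 3. Input may thus not measure copies alone, and extra copies are not excluded. Beside mat1 in series 3 the whole-cell extract difference was -2.15, and its cause was not tested. Over the probes with a single match, the immunoprecipitate differed by 3.50 in series 3 and the ratio by 5.80. A rearrangement that leaves the number of copies as it was, such as another mating type of the strain, was not tested, and the labels do not give the mating types. It stays open beside an effect of the rif1 deletion.

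The third pattern is lower H3K9me2 over the inner right end of chromosome I in the taz1 deletion. Less enrichment on the array as a whole was argued against by -3.51 after centromere scaling (SD over centromeric domains 0.75). Loss of the DNA was argued against by a whole-cell extract difference of 1.64, and signal from copies at other ends by -5.83 over probes with a single match. The input was low in wild type 1 (-2.04 against -0.40 in the taz1 deletion), which enlarged the fall of the ratio. The immunoprecipitate alone differed by -4.24. In the ratio, the rif1 deletions differed by -3.42 and -3.91 there. A dependence on Taz1 stays a hypothesis, found and tested on the same arrays, and the history of the strain was not tested.

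The deletions differed from each other (rif1 minus taz1) at the taz1 domain by -4.35 without the block. With the block they differed by -4.55 at taz1, -1.63 at tlh1, 1.77 at yhb1, -3.12 at SPBC1348.01, -3.15 at SPBC1348.08C, 3.07 at SPBPB21E7.09, 1.86 at mas2, 1.75 at nvj2, 3.47 at rpp202, 1.73 at coa6, 1.84 at the outer SPCP20C8.01C domain and 1.73 at the inner SPCC569.01C domain. Centromere scaling with the block narrowed the gaps at yhb1, SPBPB21E7.09 and coa6. It widened those at tlh1, SPBC1348.01 and SPBC1348.08C. The mating-type class (2.95) and the rDNA flanks (1.41) moved in opposite directions within series in the deletions, and this difference was not tested. Outside the main measurement, the whole-cell extract was low at ura4 in rif1 deletion 2 (-6.25 against wild type 2) and in rif1 deletion 3 (-1.92 against wild type 3), and beside mat1 in rif1 deletion 3 (-2.15 against wild type 3).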

How the results depend on the processing

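Settings chosen after seeing the data were normexp on median signals, outlier spots kept, the immunoprecipitate channel alone with or without the block, centromere scaling with the block, the taz1 and ura4 domains left out, both arrays of series 2 left out, and every recount of gene lists. Normexp on mean signals was not run, since the files hold none. The cause of a change was not tested unless given here.

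Called domains numbered 0 (taz1), 0 (rif1) and 1 (rif1 minus taz1), called probes 0 and 56, and called lists 7 and 1. With series as a block these became 33, 20 and 12 domains, 129 and 386 probes and 2 lists in rif1, and the subtelomere difference in taz1 became -1.31, since the block sets taz1 against wild type 1 alone. With slide as a random block there were 17 domains in rif1, 0 between deletions and 296 probes in rif1. Centromere scaling gave 1, 3 and 6 domains, 317 probes in rif1, 2 lists in rif1 and correlations of 0.076 and 0.17 between taz1 and rif1 of series 2 and 3. Centromere scaling with the block gave 17, 20 and 9 domains, 0 and 407 probes and 2 lists in rif1. Loess gave 1 domain in taz1, 2 between deletions, 6 and 131 probes, 2 lists in rif1, and differences in taz1 of -0.16 (mating type), 0.36 (centromeres), 0.67 (subtelomeres) and 0.24 (islands). Normexp gave 0 domains between deletions, 37 probes in rif1 and 4 and 2 lists.

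The immunoprecipitate channel alone gave 1 domain in taz1, 4 and 173 probes, and 1 and 3 lists. It turned the taz1 domain to -5.21 and the taz1 gene to -4.45 in the taz1 deletion, since the ratio there divides by missing input. With the block it gave 30, 14 and 3 domains, 107 and 375 probes and 3 lists in taz1, with -5.37 for the taz1 domain and -4.52 for the taz1 gene. Only the groups compared gave 4 domains between deletions. Domains at 2-fold gave 3 domains in rif1 and 0 between deletions. The latter count was also 0 when centred on the mode, without dim or saturated probes, with domains from the wild-type mean or the mean of group means, and with the taz1 and ura4 domains left out, where the called domain is absent. The trend and robust options gave 1 domain in taz1 and 3 and 3 probes. At an adjusted p of 0.1 there was 1 domain in taz1. Without both arrays of series 2 there were 1 domain in rif1, 0 between deletions, 43 and 316 probes and 3 lists in rif1. Spearman's rho between taz1 and rif1 of series 3 was -0.15 against r = 0.05.

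Leaving out each array in turn gave 0 to 2 domains in rif1, 0 to 2 between deletions, 27 to 309 probes in rif1, 4 to 7 and 1 to 3 lists, and differences in rif1 of -0.85 to 0.23 (islands), -1.22 to -0.13 (centromeres), -2.81 to -1.63 (subtelomeres) and 0.83 to 2.03 (mating type). Domains and probes in taz1 stayed at 0. Such omissions leave the block fit with no residual degrees of freedom if an array of series 2 or 3 is dropped. They covered the wild-type and rif1 arrays, and the lone taz1 array was not left out. Subtelomere differences in rif1 stayed negative (-2.81 to -1.31) and mating-type differences in rif1 positive (0.45 to 2.24) in each setting run, and with the mean over domains of the median over probes they were -1.34 and 0.45. Of 2828 values of single named genes or domains under other settings, 95 newly passed the threshold (limma) and 4 reversed with a call. None could stop passing it, since none of these genes or domains passed in the main fit. Another 249 changed sign without a call in either setting, 90 of them by more than the standard error. The deposited series values and the outlier spots kept changed no count by over 1.5 times. Low red signal over background in series 2 (11.3 and 11.2) limits what those arrays resolve.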

Other observations

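Domains beside the rDNA on chromosome III read higher in the rif1 deletions within series, by 0.83 in series 2 and 1.09 in series 3. With series as a block, 4 of these 7 domains rose, at SPCP20C8.01C (1.15 and 1.37) and SPCC569.01C (1.29 and 0.97). In the taz1 deletion the class differed from wild type 1 by -0.45. These domains were singled out after their values were seen.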
